A study of Homo sapiens with 6 samples.

How the data were processed

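RNA was measured in 6 libraries of U2OS cells, an established human osteosarcoma line. Per the labels' protocols, growing cells were held at the start of S phase with 4 mM hydroxyurea, which starves the replication machinery of deoxynucleotides, for 24 h, then washed and released. Cells carried siRNA against E2F7 (siE2F7) or a control siRNA with no intended target (siNT), and were taken at 0, 3 and 12 h, which stand for the G1/S transition, S phase and the G2/M boundary. Each combination of arm and time had 1 library. Per the labels' protocols, total RNA was extracted with TRIzol, cleaned on RNeasy columns and made into libraries with an Illumina TruSeq RNA kit.

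The values are FPKM (fragments scaled to transcript length and to mapped fragments) per gene, as deposited by the authors. The submitters' processing notes name CASAVA 1.8 and the hg19 (GRCh37) build. The file headers have the column layout of a Cuffdiff gene table; the aligner, the annotation and the filters are not given in the sources used here. Both libraries of a time listed the same genes in the same order, while the 3 times listed 12799, 12475 and 12299 genes at 0, 3 and 12 h, so each time had been filtered as its own pair; whether the times were scaled together is not known. In every pair the higher library of a gene was at 1.26 FPKM or more. The tables hold no counts, so the depth of the libraries is unknown and no counting error could be given. FPKM summed to between 351305 and 375954 per library, with medians from 10.07 to 10.61, and the 10 most abundant genes took 5.0% to 5.4%.

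Genes were joined by the identifiers of the tables. Of 13161 genes listed at any time, 11886 were listed at all 3 and were tested. Among these, 62 were at 0 in at least 1 library, 56 of which are small RNA entries such as snoRNAs and microRNA precursors; 143 small RNA entries were tested in all. An exact 0 can be a failed estimate, so such genes are described as listed at 0. In 9 rows a spreadsheet date number stood in place of the symbol, and these were not named. Of all 11886 tested genes, small RNA entries included, 2070 share a locus with another entry, where the reads of overlapping genes may have been split. Such genes named below include ANAPC13, CCNE2, KRT8, KRT18, MSH6, PCNA, RBL2, RFC4, RPS25, TNFRSF10B and VLDLR. Symbols are those of the tables: 10428 matched current names, 1061 matched older names and 388 matched neither. Start positions are printed counted from 1.

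The knockdown was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.1), with time as a block and arm as the term tested, a variance trend with mean expression and Benjamini-Hochberg adjustment at 0.05. The fit had 2 residual degrees of freedom and 5.4 prior degrees of freedom. All log2 changes are on this scale, which understates the change of low genes. The error of a gene joins the spread of its 3 paired ratios with the spread of genes of like expression. The latter weighs more, as 5.4 prior against 2 residual degrees of freedom. The spread of the ratios holds noise and any effect that depends on time. Nothing in the labels says that the libraries of different times came from separate experiments, so p-values measure the spread between these libraries. Gene lists, 27 in number, were tested with camera at a correlation of 0.01, with camera at an estimated correlation and with fry. Of these lists, 26 had enough measured members. Some genes are in more than 1 list, such as PCNA, EXO1 and CDKN1A, so the lists are not independent. Times were not tested against each other because nothing shows that their tables were scaled together, and the values are given without a test. Comparisons of 1 library with 1 have no replicate and no p-value. For them, and for the times, the median of a list is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins.

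The groups, the main tests, the lists, most alternatives and the rule for naming genes were fixed before the data were examined; the closing section names the alternatives and tests that were added later. The rule names E2F7, E2F8 and E2F1; per list up to 4 genes with the highest and 4 with the lowest mean ratio; the 10 highest and 10 lowest genes past the threshold with 1 direction at all times; and the 8 highest and 8 lowest ratios at single times among genes with a mean of at least 1 FPKM. The text shortens these. Some results that the rule names are withheld and are not reported. Tests meant for read counts were planned in case the tables held counts, and were not run on FPKM. Simulated data with the spread of these libraries were used to check the fit on 11886 genes. Of genes altered 1.5-fold, 2-fold and 4-fold, 80.6%, 98.5% and 100% were recovered. Of 205 calls 19 were false, a larger share than the threshold of the adjustment aims for. The simulation did not test shifts shared by many genes of a library. In the real data estimated correlations were 0.63 in the fork list and 0.88 in the ribosomal list. The simulation therefore cannot say how many of the real calls are false.

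For a closing test of siRNA seed matches, the longest 3' UTR of at least 50 bases per protein-coding gene was taken from GENCODE release 29, for sequence only, which gave a sequence to 10873 of the 11886 genes. All 16384 heptamers were ranked by a z-score of the log2 ratios at 0 h of the genes carrying them. Ratios were limited to 3 either way, and the trend with UTR length and GC content was removed. The score is the sum of the ratios over the square root of the number of carriers and the standard deviation of all genes. It thus grows with the number of carriers as well as with their mean ratio. A minimum of 30 genes per heptamer was set. The leading heptamers were also compared between genes called and not called in a fit without the 0 h libraries, on which they had been chosen. They were then examined at 3 and 12 h against 10000 random gene sets matched on UTR length. An exploratory pass with a filter on low genes ranked the overlapping copies of the leading heptamer in the other order. Shares carry exact (Clopper-Pearson) 95% intervals. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.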

Results

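Transcript levels were compared between U2OS osteosarcoma cells with siRNA against E2F7 and cells with a control siRNA, at 3 times after release from a hydroxyurea block. E2F7 is an atypical E2F transcription factor that represses E2F target genes, and the series asks which genes depend on it through the cell cycle. Each arm had 1 library at each of 0, 3 and 12 h, 6 in all. The deposited values are FPKM, and the depth behind them is unknown.

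E2F7 itself (hg19, chromosome 12, 77415026 to 77459360) was lower in every siE2F7 library than in the siNT library of its time. At 0 h it stood at 20.3 FPKM in siNT and 9.48 in siE2F7. The values were 29.4 and 10.6 FPKM at 3 h, and 16.6 and 5.52 FPKM at 12 h. The log2 change over the 3 times was -1.37 ± 0.10 (SE; limma, adjusted p = 0.001). Each library thus carried the E2F7 level its label calls for, with part of the transcript left in the knockdown.

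Across the 3 times, 1650 of 11886 genes passed the test, 803 of them higher and 847 lower in siE2F7 (limma, Benjamini-Hochberg). The genes that rose included other E2F factors and many genes of DNA replication, while those that fell included histone, inflammatory and interferon genes. Apart from small RNA entries, the largest rises were those of E2F2, MCM6, WDR76, FAM111B and ZNF367, with log2 changes of 3.51 ± 0.31, 2.27 ± 0.21, 2.15 ± 0.23, 2.10 ± 0.23 and 2.04 ± 0.15 (SE). The largest falls were those of PLA2G15, a lysosomal phospholipase, at -1.86 ± 0.12, OASL, an interferon-induced gene, at -1.81 ± 0.42 (a call lost when any 1 time was left out), AQP3, a water and glycerol channel, at -1.76 ± 0.34, and ANAPC13, a subunit of the anaphase-promoting complex, at -1.75 ± 0.13. Changes of at least 2-fold were found for 64 genes that rose and 65 that fell. Of all genes tested, 51.4% had the same sign at the 3 times, where chance gives 25%, and the 1650 all did, which their selection by the spread of the 3 ratios largely fixes. Across genes, the ratios of different times had Spearman correlations of 0.47 (0 and 3 h), 0.51 (0 and 12 h) and 0.53 (3 and 12 h), and Pearson correlations of 0.28, 0.40 and 0.41, over genes that are not independent replicates. The count was 1095 without the libraries of 0 h, 763 without those of 3 h, 852 without the variance trend and 32 with no time block. Among genes named further on, the calls of BARD1, CCL2, CLDN4, CTGF, DDX58, FANCE, HIST1H2BK, KLF2, KRT8, PPM1D, RPS25, RPS26, TBP, TNFRSF10B and TNFRSF11B each ended when the libraries of 1 or another time were left out, and AQP3, GMNN and PSAT1 lost theirs only without the variance trend or the time block. A 3' UTR copy of 1 of 2 overlapping heptamers, chosen on the 0 h ratios, was carried by 40.9% of the searched genes called lower and by 24.8% of those not called, a limit taken up in the closing section.

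Small RNA entries held 11 of the 20 most extreme places but rested on libraries listed at 0. RNU6ATAC was listed at 0 in the 3 siNT libraries and at 1.97, 1.89 and 2.41 FPKM in siE2F7. MIR1204 was listed at 0 in the 3 siE2F7 libraries and at 6.96, 7.11 and 1.76 FPKM in siNT. In all, 26 of the 1650 genes were small RNA entries.

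Several genes of the E2F family rose. Of 14 measured members of the E2F and pocket protein list, 6 rose, 0 fell and 8 did not pass (9 rose and 1 fell when adjusted over the list alone), and the median log2 change was 0.27 (camera, adjusted p = 0.00029; adjusted p = 0.41 with an estimated correlation). E2F2 went from 5.04, 1.89 and 1.30 FPKM in siNT to 26.4, 29.7 and 27.0 FPKM in siE2F7 at 0, 3 and 12 h. E2F8, the other atypical E2F, rose by 1.63 ± 0.15 and E2F1 by 1.61 ± 0.17 (SE; adjusted p = 0.0014 and 0.0023). MYBL2, a cell cycle transcription factor, rose by 0.65 ± 0.08. RBL2, a pocket protein, had a log2 change of -0.22 with an adjusted p of 0.12.

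**Figure D1:**
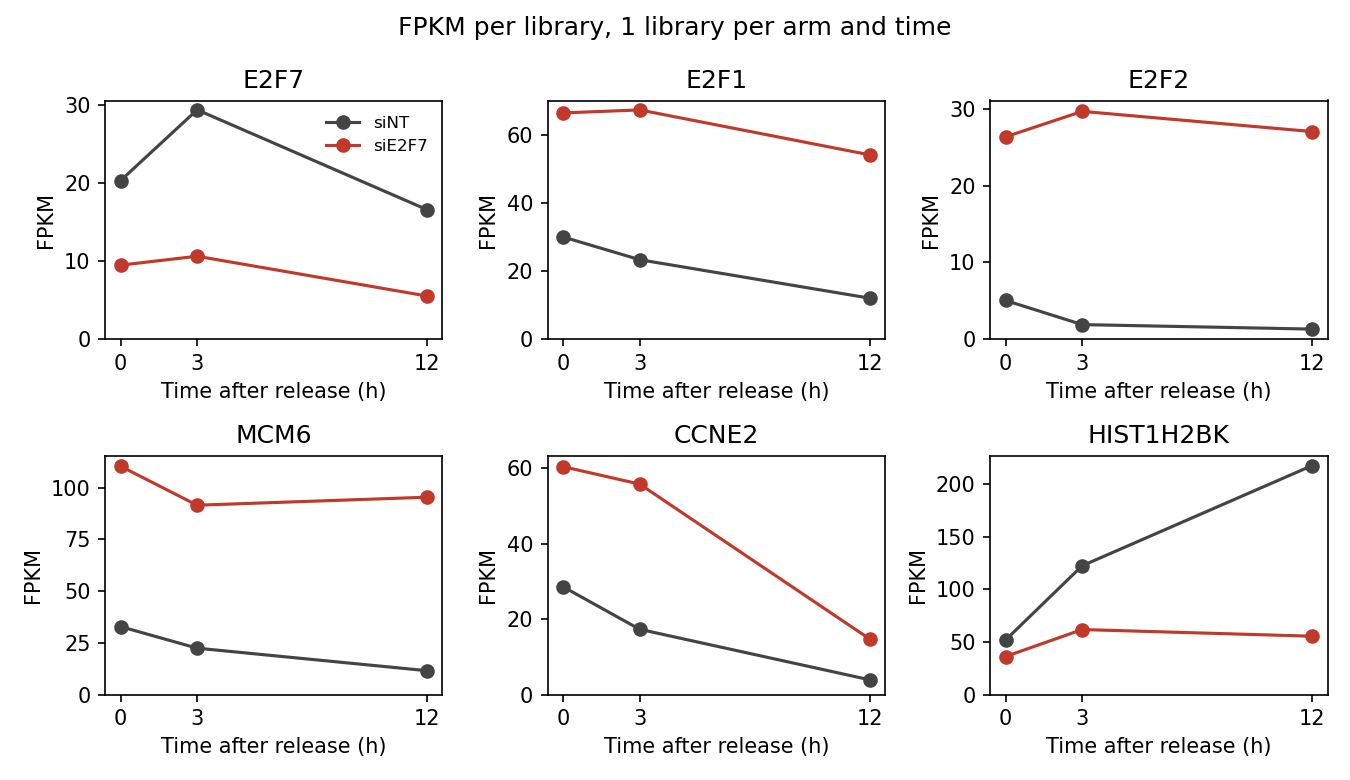
FPKM (vertical axes, from 0) of 6 genes against hours after release from hydroxyurea, with 1 point per library and lines joining the libraries of an arm. E2F7 lies lower in siE2F7 at each time, E2F1, E2F2, MCM6 and CCNE2 lie higher, and HIST1H2BK reaches 217.8 FPKM in siNT and 55.5 in siE2F7 at 12 h.

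Many genes of DNA replication rose. Of 30 members of the replication fork and polymerase list, 22 rose and 0 fell (24 and 0 adjusted over the list alone), with a median log2 change of 0.46 (camera, adjusted p = 2.1e-16; adjusted p = 0.37 with an estimated correlation). Among them were TIPIN, of the fork protection complex (1.13 ± 0.08, SE), PCNA, the sliding clamp (1.10 ± 0.14), and the clamp loader subunits DSCC1 (0.78 ± 0.09) and RFC4 (0.72 ± 0.10). Of 25 genes of origin licensing and firing, 14 rose and 1 fell (19 and 2 adjusted over the list alone), with a median of 0.51 (adjusted p = 7.6e-12; adjusted p = 0.37 with an estimated correlation). MCM6, MCM5 and MCM2 encode subunits of the replicative helicase, and the last 2 rose by 1.82 ± 0.14 and 1.27 ± 0.09. GINS2, of the same helicase, rose by 1.56 ± 0.13. The member that fell was GMNN, whose product geminin inhibits licensing, at -0.55 ± 0.09 (adjusted p = 0.011). Of 17 genes of nucleotide synthesis, 8 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.15, adjusted p = 0.00021; adjusted p = 0.37 with an estimated correlation). DUT rose by 1.46 ± 0.16, RRM2, the small subunit of ribonucleotide reductase, by 0.99 ± 0.09, DCK by 0.90 ± 0.07 and TK1 by 0.79 ± 0.10, while UMPS fell to -0.35 ± 0.08 (not called when any 1 time was left out).

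Several G1/S regulators rose. Of 20 measured, 11 rose and 0 fell (11 and 1 adjusted over the list alone), with a median of 0.40 (camera, adjusted p = 8.5e-06; adjusted p = 0.37 with an estimated correlation). The E-type cyclins CCNE2 and CCNE1 rose by 1.55 ± 0.14 and 1.05 ± 0.08, the CDK inhibitor CDKN2C by 1.30 ± 0.15 and the phosphatase CDC25A by 0.80 ± 0.08 (SE). Cyclin D1 (CCND1) had a log2 change of -0.24 with an adjusted p of 0.12.

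DNA repair lists differed in how many members passed. Homologous recombination had 10 of 30 genes that rose and 0 that fell (12 and 0 adjusted over the list alone), with a median of 0.22 (camera, adjusted p = 1.2e-05; adjusted p = 0.37 with an estimated correlation). RMI2, RBBP8 and BARD1 rose by 0.98 ± 0.12, 0.69 ± 0.08 and 0.67 ± 0.15. In the Fanconi anaemia list, 8 of 18 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.29, adjusted p = 0.00018; adjusted p = 0.37 with an estimated correlation). UHRF1 rose by 1.21 ± 0.09, FANCE by 0.61 ± 0.10 and the deubiquitinase USP1 by 0.48 ± 0.06, and FANCF fell to -0.59 ± 0.15, a call that ended with quantile normalization (adjusted p = 0.054) and when any 1 time was left out. Of 9 mismatch repair genes, 5 rose and 0 fell, in the full test and adjusted over the list alone (median 0.30, adjusted p = 0.00035; adjusted p = 0.37 with an estimated correlation). They included MSH6 (0.99 ± 0.07), EXO1 (0.55 ± 0.07), which is also in the homologous recombination list, and PCNA, which is also in the fork list. Checkpoint genes had 4 of 16 that rose and 0 that fell (6 and 0 adjusted over the list alone; median 0.16, adjusted p = 0.0033; adjusted p = 0.37 with an estimated correlation), led by CHEK1 (0.75 ± 0.08), WEE1 (0.61 ± 0.07) and TOPBP1 (0.41 ± 0.07).

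The other repair lists did not pass. For non-homologous end joining, 2 of 12 rose, in the full test and adjusted over the list alone (camera, adjusted p = 0.36). These were RIF1 (0.60 ± 0.09) and PRKDC (0.27 ± 0.07), and PRKDC was not called after quantile normalization (adjusted p = 0.057) or when any 1 time was left out. In base excision repair 5 of 18 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.13), with UNG at 0.80 ± 0.08, PARP1 at 0.38 ± 0.06 and POLB at -0.42 ± 0.11, a call that ended when any 1 time was left out. No gene of 17 in nucleotide excision repair passed, nor did any when adjusted over the list alone (adjusted p = 0.4). The camera test of base excision repair passed without genes that share a locus (adjusted p = 0.032 at the preset correlation of 0.01). Over all its measured members, camera with an estimated correlation gave an adjusted p of 0.41.

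Some genes of mitosis and chromosome structure rose. In the G2/M list 13 of 44 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 0.23 (camera, adjusted p = 3.8e-08; adjusted p = 0.5 with an estimated correlation). NUSAP1, a spindle protein, rose by 0.66 ± 0.11, separase (ESPL1) by 0.63 ± 0.10 and MKI67 by 0.57 ± 0.08. AURKA and PIF1 had log2 changes of -0.23 and -0.38 (adjusted p = 0.16 and 0.15), and both were called lower without the libraries of 12 h (-0.37 and -0.64, adjusted p = 0.029 and 0.036). Of 20 cohesin and condensin genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone; median 0.32, adjusted p = 8.3e-10; adjusted p = 0.37 with an estimated correlation), among them STAG2 (0.91 ± 0.07) and SMC2 (0.43 ± 0.07).

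Some histone, inflammatory and interferon genes fell. Of 12 listed histone genes, 0 rose and 4 fell (0 and 5 adjusted over the list alone), with a median of -0.80 (camera, adjusted p = 0.00029; adjusted p = 0.5 with an estimated correlation), and the other 45 genes of the list were not in the tables of all times. The list result thus covers 12 of 57 members and need not hold for histone transcripts as a group. HIST1H2BK and HIST1H2BC fell to -1.16 ± 0.23 and -1.01 ± 0.17, and HIST1H2BJ had a log2 change of -1.10 ± 0.41 with an adjusted p of 0.12. Of 8 inflammatory genes and NF-kB targets, 4 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.33, adjusted p = 0.00021; adjusted p = 0.37 with an estimated correlation). They were BIRC3 (-1.20 ± 0.09), CCL2 (-0.87 ± 0.17), LIF (-0.67 ± 0.09) and NFKBIA (-0.34 ± 0.09, not called when any 1 time was left out). In the interferon list 3 of 13 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.32, adjusted p = 0.011; adjusted p = 0.37 with an estimated correlation). OASL fell with the RNA sensor DDX58 (-0.81 ± 0.14), and OAS3 rose by 0.53 ± 0.13, though neither OASL nor OAS3 was called when any 1 time was left out.

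Smaller shifts were found in 2 more lists. One of cholesterol synthesis had 1 of 18 that fell, SC5DL (-0.32 ± 0.09), which did not pass after quantile normalization (adjusted p = 0.055) or when any 1 time was left out, and 0 adjusted over the list alone (median -0.17, camera, adjusted p = 0.012; adjusted p = 0.46 with an estimated correlation). One of bone markers had 2 of 8 that fell (3 adjusted over the list alone), TNFRSF11B (-0.56 ± 0.13) and ALPL (-0.37 ± 0.10), with a median of -0.19 (adjusted p = 0.032; adjusted p = 0.46 with an estimated correlation). The call of ALPL ended when any 1 time was left out, and that of TNFRSF11B without 0 h (adjusted p = 0.075) or 12 h (adjusted p = 0.054). Without the libraries of 12 h neither list passed (adjusted p = 0.053 and 0.092).

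Of the p53 targets, 3 of 28 rose and 8 fell (4 and 10 adjusted over the list alone; camera, adjusted p = 0.28). CDKN1A (0.55 ± 0.08) and PPM1D (0.40 ± 0.07) were among the former, GDF15 (-1.07 ± 0.17) and TNFRSF10B (-0.51 ± 0.12) among the latter. In the hypoxia list 3 of 16 fell, in the full test and adjusted over the list alone. CA12 stood at -1.0 ± 0.11 and NDRG1 at -0.73 ± 0.08. The adjusted p of the list by camera was 0.083, and 0.52 with an estimated correlation. At the preset correlation it was 0.028 without the libraries of 3 h, 0.041 after quantile normalization and 0.032 without genes that share a locus. The stress response list had 2 of 19 that rose and 1 that fell (camera, adjusted p = 0.55), with VLDLR at 0.86 ± 0.12 and PSAT1 at -0.35 ± 0.06, and the immediate early list had 1 of 14 each way (adjusted p = 0.78), KLF2 at 0.74 ± 0.18 and CTGF at -0.40 ± 0.09. Both counts were unaltered when adjusted over the list alone. The epithelial list had an adjusted p of 0.13 by camera, and 0.43 with an estimated correlation. At the preset correlation it was 0.03 without the libraries of 12 h. Of 6 epithelial markers 3 fell, in the full test and adjusted over the list alone, KRT8 (-0.39 ± 0.08), KRT18 (-0.34 ± 0.09) and CLDN4 (-0.66 ± 0.17). The last 2 calls ended when genes listed at only some times were let in (adjusted p = 0.052 and 0.051), and KRT18 was also not called when any 1 time was left out, CLDN4 without 0 or 3 h (0.15 and 0.18) and KRT8 without 0 or 12 h (0.066 and 0.091). Of 15 housekeeping genes 2 rose and 0 fell (2 and 1 adjusted over the list alone; adjusted p = 0.67), TBP among them at 0.39 ± 0.08. Of 70 ribosomal protein genes 2 fell (1 adjusted over the list alone), RPS26 (-0.41 ± 0.07) and RPS25 (-0.33 ± 0.08), and the list had an adjusted p of 0.17 (adjusted p = 0.83 with an estimated correlation, which was 0.88), and 1.4e-12 without the libraries of 3 h at the preset correlation of 0.01. Of the blood cell markers 1 was measured, LAPTM5, with a log2 change of -0.51 and an adjusted p of 0.21. All 16 list calls of camera were lost with an estimated correlation, where no list had an unadjusted p under 0.05. That form of the test has the 2 residual degrees of freedom of the fit, and so little power. Calls were lost also where the estimate lay under the preset 0.01, in the checkpoint (-0.06), inflammatory (-0.01) and interferon (-0.01) lists. By fry, which asks whether members move 1 way on balance, 0 lists passed after adjustment (smallest adjusted p = 0.053), and 16 were under 0.05 unadjusted.

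At single times each comparison set 1 library against 1, so the values have no replicate check. The replication lists lay higher in siE2F7 at each time, with the widest gap at 12 h: the licensing list had medians of 0.37, 0.42 and 0.63 at 0, 3 and 12 h, and the fork list 0.30, 0.54 and 0.61. None of 10000 matched random lists was as high. Random lists are matched on size and expression, not on the correlation between members. That was estimated at 0.38 in the licensing list, 0.63 in the fork list and 0.74 in the G2/M list. A shift shared by the genes of a list in 1 library could therefore also place it beyond all random lists. The difference between the 12 h and 0 h ratios had a median of 0.32 in the licensing list, 0.30 in the fork list and 0.38 in the G2/M list, each above all 10000 random lists. The 12 histone genes measured, of 57 in the list, had medians of -0.16, -0.68 and -1.37, and the last 2 medians lay below all random lists. Differences of at least 2-fold were seen for 272 genes at 0 h, 257 at 3 h and 435 at 12 h, of which 85, 68 and 75 were small RNA entries. The genes with the highest and lowest ratios were mostly listed at 0 in 1 library of the pair. RPL21, a ribosomal protein gene, was listed at 0 in siNT and at 65.05 FPKM in siE2F7 at 12 h, so a listed 0 here does not show that a transcript was missing.

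**Figure D2:**
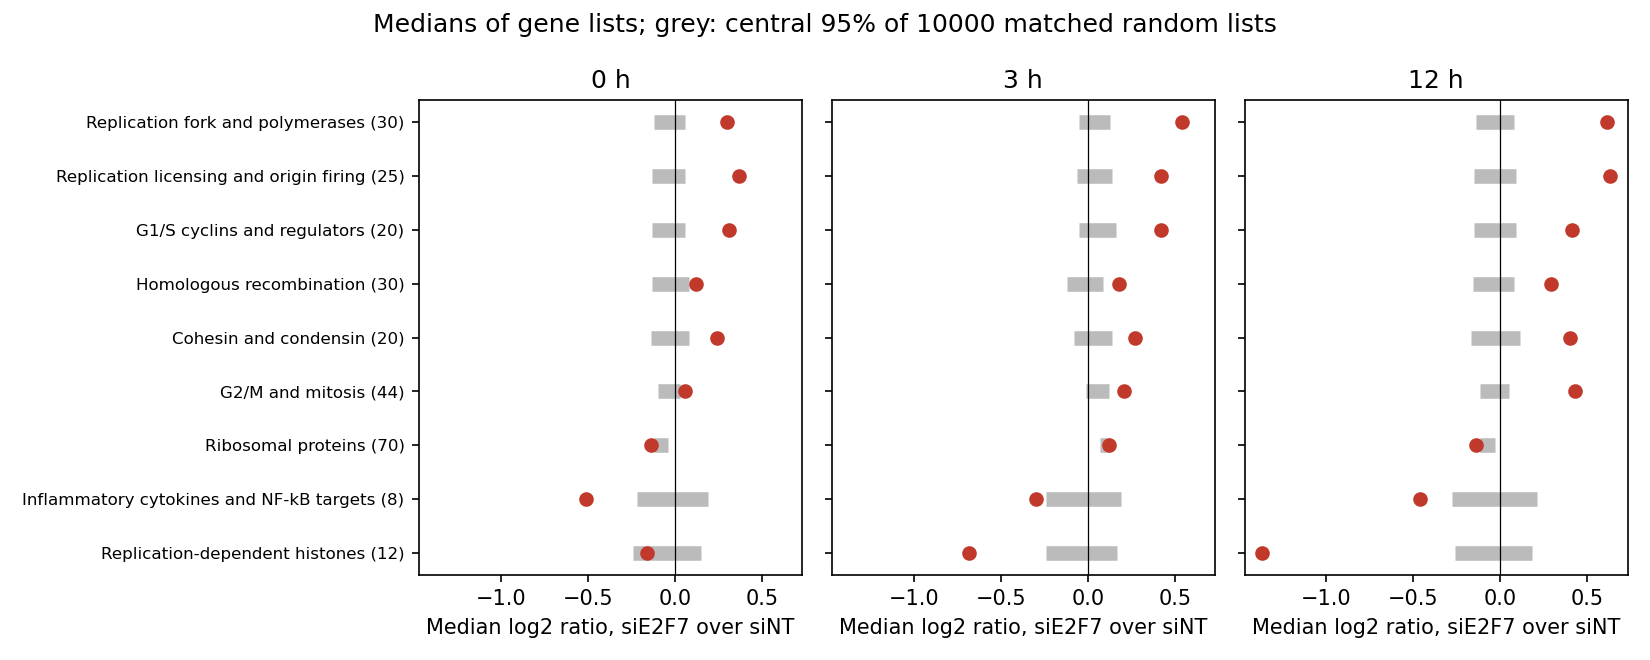
Median log2 ratio of siE2F7 over siNT (horizontal axis) for 9 gene lists (rows, with the number of measured genes) at 0, 3 and 12 h. Points are the medians and grey bars the central 95% of 10000 random lists matched on expression; the fork list stands at 0.61 and the histone list at -1.37 at 12 h.

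Across time within each arm, levels are given as values with no test. Genes of mitosis had a median log2 difference of 0.99 between 12 h and 0 h in siNT and 1.31 in siE2F7. Both lay above all 10000 random lists, which again are not matched on the correlation between members. PLK1, a mitotic kinase, differed by 1.77 in siNT and 2.47 in siE2F7, and KIF20A, a mitotic kinesin, by 1.67 and 2.20. Licensing genes had medians of -0.56 in siNT and -0.19 in siE2F7, and fork genes -0.50 and -0.25. The 12 histone genes measured, of 57 in the list, had medians of 1.59 in siNT and 0.38 in siE2F7. In siNT these 12 were higher at 12 h than at 3 h too, the time that stands for S phase (0.52). This need not hold for histone transcripts as a group. E2F1 differed by -1.31 in siNT and -0.30 in siE2F7 between the same times, and E2F2 by -1.87 and 0.04. At 3 h against 0 h, the inflammatory list had medians of 1.42 in siNT and 1.41 in siE2F7, with IL8 at 4.00 and 4.32 and BIRC3 at 3.19 and 3.12. Of 461 genes that differed at least 2-fold between 12 h and 0 h in siNT, 415 (90.0%) had the same direction in siE2F7. Nothing in the sources used here shows that the tables of the 3 times were scaled together, so levels set across times carry any difference in their scaling.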

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

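The results here had opposite directions at different times; none of these differences was tested, since each time has 1 pair of libraries. The size limit for lists and the choice of genes were set after the values had been seen. Ribosomal protein genes had a median log2 ratio of siE2F7 over siNT of -0.14 at 0 h, 0.12 at 3 h and -0.14 at 12 h.

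Among genes with large ratios at single times, 3 entries that are not small RNAs changed places between arms. TEX101 stood at 5.38 FPKM in siNT and 0.326 in siE2F7 at 0 h, and at 0.29 and 3.63 FPKM at 12 h. The readthrough entry MUTED-TXNDC5 stood at 7.93 FPKM in siNT and 0.00187 in siE2F7 at 0 h, and was listed at 0.0 in siNT and 8.1 FPKM in siE2F7 at 3 h. The readthrough entry TGIF2-C20ORF24 stood at 3.79 FPKM in siNT and 0.00391 in siE2F7 at 0 h, and was listed at 0.0 in siNT and 6.27 FPKM in siE2F7 at 3 h.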

How the results depend on the processing

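Settings fixed beforehand changed the pseudocount, the filter on low values, the scaling (quantile normalization), the block, the threshold and the times used; leaving out small RNA entries, genes at 0, genes that share a locus or genes with a heptamer copy, centring on medians and dropping the variance trend were chosen after seeing the data. E2F7 was lower under each alternative that could include it, with log2 changes from -1.28 to -1.52 over the fits. With no time block its change of -1.37 had an adjusted p of 0.12, and 32 genes passed in place of 1650, because the differences between times then count as noise. At an adjusted p under 0.1 the count was 2683. It was 852 without the variance trend, where the cause was not tested, and 913 without genes whose 3' UTR carries a heptamer copy, with 8935 genes tested (507 higher and 406 lower, against 803 and 847). Leaving out the libraries of 0, 3 or 12 h gave 1095, 763 and 1109 genes, with fewer samples. Genes shared with the 1650, in the same direction, numbered 962, 695 and 982. Under the other settings counts lay between 1566 and 2005, and over all settings but the block the share of higher genes, 48.7% here, lay between 43.5% (without 3 h) and 55.5% (without heptamer carriers). Of the 16 list calls, 0 held with an estimated correlation and 0 with fry. The checkpoint, inflammatory and interferon lists had estimated correlations of -0.06, -0.01 and -0.01, under the preset 0.01. A higher correlation therefore does not account for the loss of their calls. The estimates of the other lists called lay above 0.01. With an estimated correlation the test has the 2 residual degrees of freedom of the fit, and so little power. The cause was not tested further.

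Lists near 0 turned the direction that camera gives, which follows all members rather than the median. Their medians were these: the immediate early list stood at 0.01 and the ribosomal list at -0.01 without 0 h, the housekeeping list at -0.1 without 3 h, the ribosomal list at 0 without 12 h, and the stress response list at -0.04 without heptamer carriers. The ribosomal list stood at -0.14 without 3 h, the immediate early list at -0.05 and the housekeeping list at 0.02 without 12 h. The cause was not tested. At single times, 140, 149 and 250 genes differed at least 2-fold at 0, 3 and 12 h with a pseudocount of 1, 33, 49 and 75 with a pseudocount of 5, and 66, 101 and 177 at a mean of at least 5 FPKM, since these settings shrink or drop low genes. Tests for read counts and alternatives by library size or size factors were not run, as the values are FPKM, nor were those for comparisons between times. No paired analysis was possible by replicate, because each arm holds 1 library per time; the fit pairs the arms by time alone. Unknown depth leaves the error of low genes open.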

Other observations

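The test of a heptamer at later times, those of its share in called genes by Fisher's test, that of copies in the replication lists and that of the cell cycle delay were chosen after their results had been seen; the other tests were set before. The test of copies replaced a planned one, the lists without carriers, which left out too few genes to decide anything and whose first run had taken in the histone list by its name. In the split test, 1 of 10 splits of the 6 libraries into 3 and 3, the real one, gave 1650 genes, and the highest of the others gave 0. With 10 splits no share can be under 0.05.

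The genes here stand outside the fixed lists, were higher in siE2F7 at each time and are named after their values had been seen. PIM1, a kinase gene, stood at 12.2 FPKM in siNT and 37.3 in siE2F7 at 0 h, at 25.1 and 84.8 FPKM at 3 h, and at 17.2 and 50.5 FPKM at 12 h. NTN1, which encodes the guidance cue netrin, stood at 5.68 and 16.6 FPKM at 0 h, 4.05 and 13.9 FPKM at 3 h, and 1.77 and 10.3 FPKM at 12 h.

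A first pattern is a short sequence among the genes lower in siE2F7: of all 16384 heptamers, CTCTGGA and its shifted copy ACTCTGG ranked 1 and 2 for lower ratios in the 3' UTR at 0 h, and again held the first 2 ranks at 3 h and 12 h. Genes with CTCTGGA had a median ratio of -0.057 at 3 h, and -0.082 at 12 h, below the central 95% of random sets, which ended at -0.027 and -0.033. Seed matches to an siRNA used against E2F7 may therefore lower part of these genes. Copies of CTCTGGA or ACTCTGG were found in 40.9% (exact 95% interval 37.5 to 44.4) of the 811 searched genes called lower. This argues against direct matches to this heptamer in their own 3' UTRs as the cause for all of them. Indirect effects of such matches were not tested, and seeds of other strands or siRNAs stay open. Genes called without the 0 h libraries, on which the heptamer was chosen, were also compared. The shares were 41.8% of 507 lower genes and 25.2% of 9844 not called (Fisher's exact test, two-sided, p = 2.4e-15). This test takes genes as independent and does not match them on UTR length or GC content, so its p-value only describes these genes. Of the falls named in the report, PLA2G15, AQP3, GMNN, GDF15, DDX58, LIF, CA12, UMPS, SC5DL, ALPL, RPS26, KRT8, CLDN4 and E2F7 carry a 3' UTR copy of either sequence. ANAPC13, OASL, BIRC3 and others do not. E2F2, EXO1, CDKN1A, OAS3 and VLDLR, which rose, carry a copy, as did 20.4% of all searched genes called higher. Counted over whole transcripts rather than the 3' UTR, 47.4% of those of about the length of E2F7 hold CTCTGGA. The siRNA sequences are not given in the sources used here, so the link stays a hypothesis.

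A second pattern is the rise of replication genes. TGACGTA ranked 1 for higher ratios at each time. It or its shifted copy GACGTAA was carried by 10.0% of 522 searched genes called higher without the 0 h libraries, on which it was chosen. The share was 2.0% of 9844 not called (Fisher's exact test, two-sided, p = 1e-18, again with genes taken as independent and unmatched). A seed match of the control siRNA could give this. Of 55 searched members of the licensing and fork lists, 1 carries a copy (1.8%, exact 95% interval 0.0 to 9.7). That is near the 1.9% of genes not called in the full test. It argues against direct matches to this heptamer in the members' own 3' UTRs as the cause there. Indirect effects of such matches were not tested, and other seeds stay open. A delay of siE2F7 cells at 12 h would lower G2/M genes only if siNT cells had not yet divided. The G2/M list stood at percentile 100 there. How many siNT cells had divided by 12 h is not known, and a direct effect of the siRNA on G2/M genes could hide a delay. The test therefore does not decide on a delay, nor on a difference in phase at 0 or 3 h. Loss of repression by E2F7 remains open as a biological explanation, which these libraries do not separate from other effects of the siRNA.

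A further pattern is the small RNA entries that differ at least 2-fold at a time. Of 92 such entries, 50 (54.3%, exact 95% interval 43.6 to 64.8) kept their direction at the next time, against 218 of 251 other entries (86.9%, 82.0 to 90.8). This is consistent with short or unstable estimates rather than a response. No biological explanation was tested.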
